A study of Mus with 4 samples.

How the data were processed

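Circular RNAs (circRNAs) are closed RNA rings made when a splice donor joins an upstream acceptor, and a read across that back-spliced junction comes from such a molecule. Ocular tissue was taken from C57BL/6J mice, wild type or with a deletion of VLDLR, the very-low-density lipoprotein receptor. The pups had breathed 75% oxygen from postnatal day 7 (P7) to P12, and tissue was taken at P12 or, after 1 day in room air, at P13, per the labels. In every comparison of the days, age and the return to room air therefore cannot be told apart. Each of the 4 groups held 1 library, so that no comparison within a group was possible. Per the labels' protocols, ribosomal and linear RNA were removed from total RNA, and the remainder was fragmented and sequenced in pairs on an Illumina instrument. The labels do not say how many animals a library holds.

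The deposited tables give for each library the count of back-spliced junction reads per circRNA, its class (exon, intron or intergenic) and its host gene identifiers. They also give the count of non-junction reads at the same splice positions, in the column layout of the caller CIRI per the file headers. The deposited junction ratio is a fraction, and recomputing it showed that the authors divided 2 times the junction reads by 2 times the junction reads plus the non-junction reads. The deposited SRPBM values are a signal in which the authors divided the junction reads by 1 constant per library. SRPBM summed to 72488 in wild type P12, 83421 in wild type P13, 28235 in deletion P12 and 28344 in deletion P13. What the constant counts is not given in the sources used here. BWA and DESeq2 are named in the submitters' processing notes, with no version or role. The genome build and annotation are not given in the sources used here, and coordinates below are those of the deposited tables. Each table listed circRNAs with at least 2 junction reads. An unlisted circRNA can hold 1 read, or more if the caller left it out. Where the class or host of a circRNA differed between tables (50 of 44073 circRNAs), exon was taken before intron and intron before intergenic.

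Host identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, and between 99.83% and 99.87% of the identifiers per library matched. Of the circRNAs with 1 matched host, between 99.96% and 99.98% per library lay inside the interval of that host in the table, which was used for names only. CircRNAs of Vldlr were not analysed here, because the count was 0 in all 4 libraries, and the targeted gene therefore gave no check of the labels. The junction reads carry their instrument run and lane in their identifiers. The wild-type libraries shared 1 run on 2 lanes and the deletion libraries another run on 1 lane. With 0 runs shared between the genotypes, genotype and sequencing run cannot be told apart.

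Junction counts were scaled with edgeR's TMM method over the circRNAs with at least 10 reads in at least 2 libraries. The reads of these (562078, 640636, 260797 and 296072 for wild type P12, wild type P13, deletion P12 and deletion P13) were multiplied by factors of 1.017, 1.011, 0.9911 and 0.9817 to give effective library sizes. For each pair of single libraries the ratio of scaled counts was computed with an exact conditional (Clopper-Pearson) 95% interval. CircRNAs with at least 20 reads over the 2 libraries were tested. One was called higher or lower where the ratio was at least 2 or at most 0.5 and the interval excluded 1. These calls compare 2 libraries and not the conditions, carry no p-value and have no replicate check. Intervals cover counting error only, since the reads have no molecular identifiers. The number of calls in 20 Poisson simulations of unchanged libraries is given beside each count. These simulations hold counting error and no spread between libraries, so that an excess over them is not by itself a change between conditions. On simulated data, with 2-fold changes the rule recovered 42%, 27%, 44% and 45% of changed circRNAs for the genotype at P12, the genotype at P13, the day in wild type and the day in the deletion. With 4-fold changes it recovered 88%, 93%, 89% and 94%. Against an unlisted circRNA the fold is given as a bound computed with 3 reads per library, which leaves out the counting error of the listed library. The exact interval reaches lower, to 75.0 against 93.6 for the Fbxw4 circRNA named for the genotype at P12. An unlisted circRNA can hold 1 read, or more if the caller left it out. The interval takes it as 0, so that both values can be too high. The folds given below as "at least" are bounds only where the circRNA was absent from the library. They are none where the caller left it out, and the counts do not tell these cases apart.

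The single design with a test used all 4 libraries: edgeR's quasi-likelihood test (glmQLFit, robust) with genotype and day as additive terms. It covered the 8785 circRNAs with at least 10 reads in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom and takes the change with day to be alike in both genotypes, so that p-values measure only the spread left between these 4 libraries. The biological coefficient of variation was 0.213. On simulated data of that spread the genotype test recovered 9% of 2-fold and 63% of 4-fold changes, and the day test 9% and 70%. The same test was run on reads summed over 3899 host genes.

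The 20 lists of host genes (cell types of the eye, pathways and known circRNA hosts; 842 entries, 821 distinct genes, 21 of them in more than 1 list) were fixed before the data were examined, as were the groups, tests, alternatives and the rule for named circRNAs. For each pair of libraries the median log2 ratio over a list's host genes, with 0.5 added to each count, was placed among 10000 random lists of the same size matched on level. Named circRNAs were, per pair, taken from the 10 called higher and the 10 called lower with a host gene whose interval bound nearest to 1 lay farthest from it. In the fits they were the 10 with the smallest p per direction, and for calls shared by both days or both genotypes the 5 per direction with the largest smaller bound. The 10 most abundant circRNAs and up to 4 members per list (the 2 with the most reads and the 2 with the largest change) could also be named. Other list members, named because they passed the test, were chosen after their values were seen. Some circRNAs and genes that these rules pick are not used here.

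Alternatives were scaling by total junction reads, by SRPBM or by DESeq2 size factors, other read minimums, thinning to the smaller total, exonic circRNAs alone, sums per host gene, DESeq2's Wald test, no additive term and leaving out each library. Added after seeing the data were circRNAs listed in both (or all 4) libraries, and counting once those reads of 1 junction that lay within 2500 coordinate units of each other on the flow cell (7.09% to 7.22% of reads). SRPBM scaling moved the median log2 ratio by -1.36 for the genotype at P12, -1.56 for the genotype at P13, 0.188 for the day in wild type and -0.0150 for the day in the deletion. All directions below are relative to the median circRNA unless SRPBM is named. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.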

Results

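Back-spliced junction reads were listed for 28563 circRNAs in wild type P12, 31208 in wild type P13, 18022 in VLDLR deletion P12 and 20129 in VLDLR deletion P13. The libraries held 662811, 759063, 299723 and 341873 junction reads in the same order, with a median of 6, 6, 5 and 5 reads per circRNA. After thinning every library to 299723 reads, 20831, 21096, 18022 and 19097 circRNAs were detected. Of 44073 circRNAs in all, 11114 were listed in every library and held 87.0% of the reads. Of all circRNAs 18636 were listed in wild type alone, 4734 in the deletion alone and 20703 in both genotypes. They came from 7146 host genes.

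Gigyf2, Ano2, Phf21a, Bbs9, Hipk3, Tulp4, Mettl9, Snrk and Arhgap10 hosted 9 of the 10 most abundant circRNAs. The most abundant one was intergenic (chromosome 10, 92075170 to 92136690; 6917, 8525, 2781 and 2884 reads in wild type P12, wild type P13, deletion P12 and deletion P13). The Gigyf2 circRNA (chromosome 1, 87364104 to 87380008, exon class) held 4686, 5253, 2142 and 2619 reads. The Ano2 circRNA, from a calcium-activated chloride channel gene (chromosome 6, 125710556 to 125712447, exon class), held 3825, 5190, 2019 and 2318. The 10 most abundant took between 5.75% and 6.15% of the reads of a library. Exonic circRNAs made up 88.1% of circRNAs in wild type P12 (95% exact binomial interval 87.7% to 88.5%), 87.8% in wild type P13 (87.4% to 88.2%), 88.7% in deletion P12 (88.3% to 89.2%) and 88.3% in deletion P13 (87.8% to 88.7%). Intronic circRNAs made up between 6.60% and 7.06%, and the remainder were intergenic. Over 2193 circRNAs with at least 20 reads in each library the median junction ratio was 0.624, 0.634, 0.629 and 0.627 in the same order. Within circRNAs the median difference between deletion and wild type was 0.00752 at P12 and 0.00195 at P13, and between P13 and P12 it was 0.00481 in wild type and -4.30e-04 in the deletion.

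The genotype was first compared over both days. In the VLDLR deletion, circRNAs of the lens gene Bfsp1, the Mediator subunit gene Med13l, Atxn1 and the splicing factor gene Srsf1 rose. CircRNAs of Eipr1, Neurl1a, Ptpn21, Ip6k2, the kinesin gene Kif1b, Anks1b and the histone demethylase gene Kdm4b fell. Photoreceptor hosts had 19 circRNAs that rose and 1 that fell of 148 tested. Of all 8785 circRNAs tested, 442 rose and 315 fell by edgeR's quasi-likelihood test (977 and 834 at an unadjusted p under 0.05). DESeq2 called 187 and 102, and 286 circRNAs passed both tools in the same direction. On the SRPBM scale 25 rose and 4773 fell. Of the 442 that rose relative to the median circRNA, 199 were also above wild type on that scale and 68 were called lower there. Without wild type P12 the counts were 267 and 200, and without wild type P13 256 rose. The count that fell was 675 without deletion P12 and 881 without deletion P13. Genotype and sequencing run cannot be told apart in these libraries.

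The Bfsp1 circRNA (chromosome 2, 143841674 to 143849023, exon class), whose host encodes the lens fibre protein filensin, had a log2 fold change of 4.36. It held 43 and 57 reads in wild type P12 and P13 and 518 and 411 in deletion P12 and P13. The Srsf1 circRNA (chromosome 11, 88049977 to 88053039, exon class) went from 10 and 17 reads to 74 and 76 (3.62), and an intergenic one (chromosome 9, 63093427 to 63093625) from 41 and 39 to 163 and 131 (3.02). Med13l (chromosome 5, 118593333 to 118593570, exon class) had 403 and 347 reads in wild type and 782 and 657 in the deletion (2.09). Atxn1 (chromosome 13, 45852328 to 45956575, exon class) had 77 and 82 against 223 and 193 (2.53). Smaller rises were those of Bbs9, a subunit gene of the BBSome (chromosome 9, 22887581 to 22887996, exon class; 1.53), and BC046251 (chromosome 7, 65613537 to 65615126, intron class; 2.08). Eri3 (chromosome 4, 117582600 to 117593162, exon class; 1.47) and an intergenic circRNA (chromosome 6, 67077248 to 67116767; 1.53) rose as well. Adjusted p for these circRNAs ran from 9.37e-10 for Bfsp1 to 8.81e-07 for Eri3 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

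An intergenic circRNA (chromosome 15, 84171082 to 84186081) held 202 and 227 reads in wild type P12 and P13 and was unlisted in the deletion. It was at least 30.5-fold lower at P12 and at least 34.0-fold at P13. A circRNA of Wdr78, an axonemal dynein chain gene (chromosome 4, 103095329 to 103096775, exon class), went from 97 and 142 reads to unlisted, at least 21.2-fold lower at P13. It did not pass DESeq2 (adjusted p 0.337 by DESeq2 against 1.14e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Kif1b (chromosome 4, 149245338 to 149253751) fell from 259 and 300 reads to 10 and 19, a log2 fold change of -3.13. Ip6k2 (chromosome 9, 108796064 to 108796396) fell from 309 and 268 to 18 and 17 (-2.89). Neurl1a (chromosome 19, 47239802 to 47240671; -2.55), Eipr1 (chromosome 12, 28859252 to 28867153; -2.42) and Tmcc1 (chromosome 6, 116042871 to 116043805; -2.36) fell. Ptpn21 (chromosome 12, 98733474 to 98733834; -2.22), Kdm4b (chromosome 17, 56351633 to 56356056; -1.83) and Anks1b (chromosome 10, 90069468 to 90077142; -1.50), all of the exon class like those of Kif1b and Ip6k2, completed the 10. Their adjusted p ran from 1.07e-07 for the intergenic circRNA to 1.65e-06 for Kdm4b (edgeR's quasi-likelihood test, Benjamini-Hochberg).

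**Figure D1:**
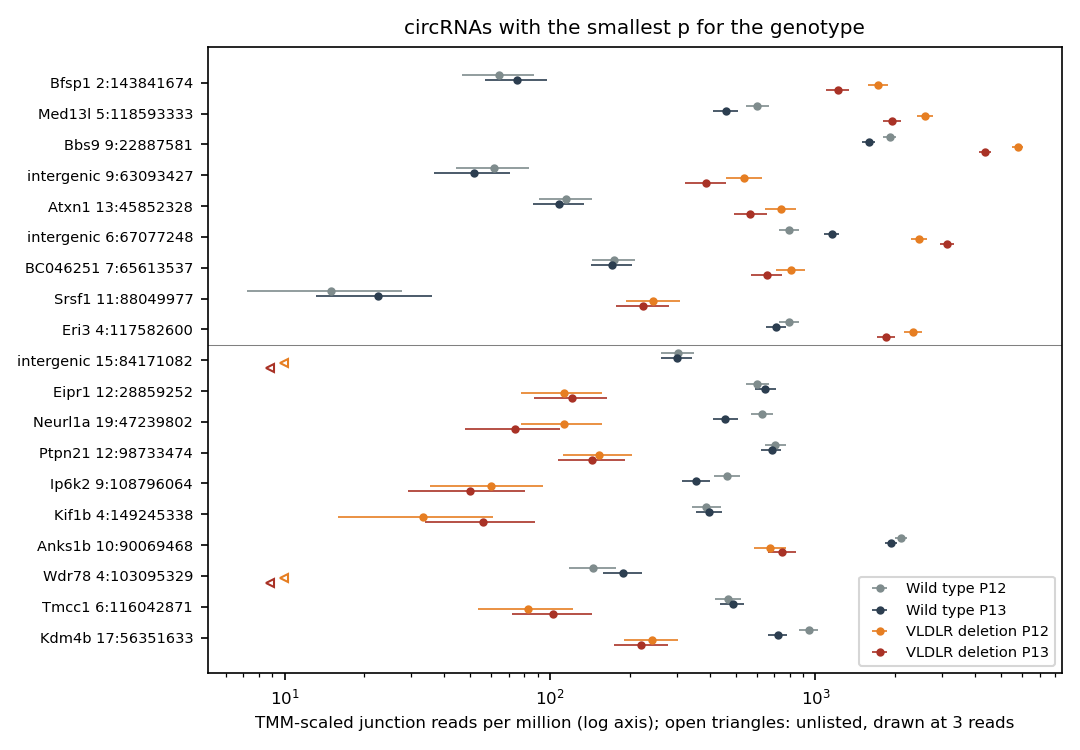
Scaled junction reads (log axis, TMM) of circRNAs with the smallest p for the genotype, with 95% Poisson intervals and 1 point per library; labels give host, chromosome and start. Those above the grey line lie higher and those under it lower in both deletion libraries than in both wild-type libraries on this scale, and open triangles mark unlisted circRNAs at 3 reads.

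In most hosts with a call, some tested circRNAs did not pass. Of 9 tested Atxn1 circRNAs 5 rose and 4 did not pass, and of 17 from Anks1b 4 fell. Bbs9 had 2 that rose and 5 that fell among 24, and Kif1b 1 that fell among 16. Across the genome 331 host genes held a circRNA that rose, 257 one that fell and 33 both. Among 437 hosts with a call and at least 2 tested circRNAs, every tested circRNA was called in 9. The test recovered 9% of 2-fold and 63% of 4-fold changes on simulated data, so that circRNAs that did not pass can have changed too. Of 555 hosts with a called circRNA, 368 were called on summed reads. On reads summed per host, Bfsp1 rose (log2 2.09) and so did the arrestin gene Sag (1.78), with adjusted p of 2.10e-56 and 2.42e-37 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These p-values rest on 1 residual degree of freedom and measure only the spread left between these 4 libraries, not that between animals. On the SRPBM scale Bfsp1 stood at 0.57 and Sag at 0.26, and Sag did not pass there (adjusted p 0.172 by the same test).

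Photoreceptor circRNAs that rose included those of Sag, Rpgrip1, Pde6a, Impg2, Prom1, Cngb3 and Cacna2d4, although 77 photoreceptor circRNAs fell and 3 rose on the SRPBM scale. Of the 19 that rose, 10 were above wild type there and 3 were called lower, and those of Prom1, Cngb3 and Cacna2d4 were below wild type. Adjusted over the list alone, 20 rose and 2 fell, and at an unadjusted p under 0.05 by edgeR 26 and 8, while DESeq2 called 12. The list median was inside the middle 95% of matched random lists (0.188 at P12, percentile 93.1, and 0.148 at P13, percentile 93.5). The strongest Sag circRNA (chromosome 1, 87828397 to 87834627, exon class) held 40 and 81 reads in wild type and 207 and 187 in the deletion (log2 2.89). Rpgrip1 had one with 51 and 39 against 116 and 64 (chromosome 14, 52156153 to 52158454), and Pde6a, a rod phosphodiesterase gene, one with 27 and 34 against 42 and 60 (1.88). Their adjusted p were 1.19e-05 for Sag, 1.98e-05 for Rpgrip1 and 5.20e-04 for Pde6a (edgeR's quasi-likelihood test, Benjamini-Hochberg). Summed per host, Sag, Pde6a, Pde6b and Gucy2f rose and none of 26 photoreceptor hosts fell by edgeR's test (1 at an unadjusted p under 0.05). On the SRPBM scale Sag was above wild type (0.26) and Pde6b below it (-0.15), and neither passed. Pde6a (-0.60) and Gucy2f (-0.83) were called lower there (adjusted p 0.0159 and 0.00222 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

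Synapse hosts had 13 circRNAs that rose and 1 that fell of 185 (12 and 1 adjusted over the list alone). At an unadjusted p under 0.05 by edgeR these counts were 23 and 11, and DESeq2 called 5. On the SRPBM scale they were 1 and 102, with 3 of the 13 above wild type. Rims2, which encodes an active-zone protein, rose from 172 and 260 reads to 174 and 254 in the smaller deletion libraries (chromosome 15, 39610064 to 39616510; log2 1.14, but -0.32 on the SRPBM scale). Dgki went from unlisted to 18 and 20 reads (chromosome 6, 37087629 to 37149657). The neuroligin gene Nlgn1 gave the circRNA that fell (chromosome 3, 26133242 to 26134052; 440 and 393 reads against 91 and 111). Hosts of widely studied circRNAs had 16 that rose and 8 that fell of 204 (16 and 14 adjusted over the list alone). At an unadjusted p under 0.05 by edgeR there were 27 and 25, and DESeq2 called 11. On the SRPBM scale there were 0 and 122, with 7 of the 16 above wild type. Among them Hipk3 (chromosome 2, 104470749 to 104471847, exon class) fell by 0.59 on the log2 scale from 3989 and 4372 reads to 1113 and 1409. Ttc3 (chromosome 16, 94383912 to 94393174) fell from 910 and 910 reads to 183 and 213, and Itch rose by 1.92.

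Hypoxia-response hosts had 4 circRNAs that rose and 3 that fell of 37 (5 and 3 adjusted over the list alone, on the SRPBM scale 0 and 23). At an unadjusted p under 0.05 by edgeR the counts were 8 and 3, and DESeq2 called 5. Kdm4b and Foxo3 fell (Foxo3 on chromosome 10, 42196466 to 42197901; 94 and 101 reads against 7 and 10; log2 -2.36). Ldha, a lactate dehydrogenase gene (chromosome 7, 46850178 to 46851058; 0.70), and Zfp292 (0.62) rose relative to the median circRNA, and Kdm4c had 2 that rose and 1 that fell. On the SRPBM scale those of Ldha (-0.76) and Zfp292 (-0.84) and 1 of the 2 from Kdm4c were called lower. Cell-cycle hosts had 3 that rose and 0 that fell of 24 (3 and 0 adjusted over the list alone and 8 and 0 at an unadjusted p under 0.05 by edgeR, with 2 called by DESeq2; on the SRPBM scale 0 rose and 4 fell, with 2 of the 3 above wild type). They came from the DNA polymerase gene Pola1 (chromosome X, 93620505 to 93626612; 201 and 187 reads against 230 and 227), the spindle checkpoint gene Bub1b and Prim2. Hosts of RNA-binding proteins had 3 that rose and 1 that fell of 76 (3 and 1 adjusted over the list alone, 9 and 4 at an unadjusted p under 0.05 by edgeR, 2 by DESeq2). On the SRPBM scale there were 0 and 38, with 1 of the 3 above wild type. Pum2 was among those up and Mbnl2 was down (chromosome 14, 120324794 to 120325412; log2 -1.02). Striated-muscle hosts had 4 that rose and 0 that fell of 59 (4 and 0 adjusted over the list alone, 9 and 1 at an unadjusted p under 0.05 by edgeR, 1 called by DESeq2; 0 and 24 on the SRPBM scale). They came from Dmd, Phkb and Fhod3, and that of Phkb was called lower on the SRPBM scale.

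Lens hosts had 2 that rose and 0 that fell of 18, both from Bfsp1 (2 and 0 adjusted over the list alone, 2 and 1 at an unadjusted p under 0.05 by edgeR, 2 by DESeq2; 1 and 9 on the SRPBM scale, with 1 of the 2 above wild type). On summed reads the crystallin gene Cryga fell from 45 and 158 reads to 4 and 8 (log2 -2.79) and Prox1 fell by 0.69, so that the lens hosts moved apart. Endothelial hosts had 1 circRNA that rose of 27, from the semaphorin receptor gene Plxnd1 (chromosome 6, 115969876 to 115970248; 9 and 5 reads against 27 and 19; log2 2.85), and 0 that fell (1 and 0 adjusted over the list alone, 2 and 1 at an unadjusted p under 0.05 by edgeR, 1 by DESeq2; 0 and 9 on the SRPBM scale). Wnt hosts had 1 up (Invs) and 1 down (Ryk) of 36, as when adjusted over the list alone (1 and 5 at an unadjusted p under 0.05 by edgeR, 0 by DESeq2; 1 and 23 on the SRPBM scale). Lipoprotein-receptor and lipid hosts had 1 up of 49, Sorcs1 (chromosome 19, 50252534 to 50262367; below wild type on the SRPBM scale), and 0 down (1 and 0 adjusted over the list alone, 3 and 3 at an unadjusted p under 0.05 by edgeR, 0 by DESeq2; 0 and 24 on the SRPBM scale). Summed per host, Sorcs1, Lrp1b and Ldlrad3 rose and Abca1, Acsl1 and Ppara fell. On the SRPBM scale Sorcs1 (-0.52) and Lrp1b (-0.69) were called lower, and Ldlrad3 (-0.43) was below wild type without passing. Reln, Dab1 and Lrp8, which act with VLDLR in Reelin signalling, had log2 fold changes of 0.01, 0.29 and -0.23 that did not pass (adjusted p 0.99, 0.732 and 0.768 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Erythroid hosts had 1 up of 2, from Tfrc, and 0 down (1 and 0 adjusted over the list alone and at an unadjusted p under 0.05 by edgeR, 0 by DESeq2; 0 and 1 on the SRPBM scale, where that of Tfrc was below wild type).

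No circRNA of the remaining 8 lists passed over all circRNAs tested by edgeR's test, and DESeq2 called 0 in each. Bipolar-cell hosts had 16 tested and 3 up and 1 down adjusted over the list alone, the same as at an unadjusted p under 0.05. On summed reads Trpm1 and Lrit3 rose. On the SRPBM scale, however, Trpm1 was called lower (-0.71) and Lrit3 was below wild type without passing (-0.23). There 0 bipolar-cell circRNAs rose and 6 fell. For the other 7 the count adjusted over the list alone was 0. At an unadjusted p under 0.05, 3 of 13 circRNAs of retinal pigment epithelium and melanocyte hosts and 1 of 7 of microglia and leukocyte hosts were higher, and 2 of 12 of Müller glia hosts were lower. At that threshold 0 passed among 8 of amacrine, horizontal and ganglion cell hosts and among 1 each of corneal, fibroblast and pericyte hosts.

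At P12, circRNAs of Fbxw4, Bfsp1, Pcsk6, Ambra1, Pik3c2a and the ubiquitin ligase gene Nedd4 were called higher in the deletion library. CircRNAs of Spopl, the nuclear receptor coactivator gene Ncoa2, Emc2, Zfand6, Ube2cbp, Sltm and Pak3 were called lower. Fbxw4 (chromosome 19, 45624376 to 45640521, intron class) had 127 reads against unlisted in wild type P12, at least 93.6-fold higher. It had 172 and 121 reads in wild type and deletion P13. Bfsp1 was 26.6-fold higher (95% counting interval 19.5 to 37.2), Pik3c2a (chromosome 7, 116358636 to 116360100) 27.0-fold (14.2 to 57.7) and Pcsk6 (chromosome 7, 65910202 to 65983849) 71.8-fold (19.1 to 606). Nedd4 (chromosome 9, 72731222 to 72735239) was unlisted in both wild-type libraries and had 25 reads in deletion P12, at least 18.4-fold higher. Spopl (chromosome 2, 23537328 to 23545579) had 554 reads and Ncoa2 (chromosome 1, 13177074 to 13224713) 494 in wild type P12. Both were unlisted in the other 3 libraries, at least 83.5-fold and 74.5-fold lower in deletion P12. Emc2 (chromosome 15, 43492170 to 43513849) had 336 reads in wild type P12, none listed in deletion P12, and 426 and 157 in the P13 libraries. For Fbxw4, Spopl, Ncoa2 and Emc2, 1 library thus differed from the other 3 in whether the circRNA was listed. Their calls rest on that library. Of 7261 circRNAs tested, 795 were called higher and 769 lower, against 67.7 and 77.3 in simulated unchanged libraries. Of those lower, 174 were unlisted in the deletion. On the SRPBM scale the split was 63 and 4660.

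At P13, circRNAs of the potassium-chloride cotransporter gene Slc12a5, Epb41l2, Invs, Dpp6, Nedd4, Bfsp1 and Kmt2a were called higher in the deletion library. CircRNAs of the mismatch repair gene Pms1, Rbbp4, Phkb, Wdr78, Tle4, Slc17a5 and Bbs9 were called lower. Slc12a5 (chromosome 2, 164973687 to 164974579) had 75 reads against 2, 83.6-fold higher (95% counting interval 22.3 to 703). Kmt2a (chromosome 9, 44809715 to 44816659) was 19.7-fold higher (8.47 to 56.0), Bfsp1 16.1-fold (12.2 to 21.6), and Invs (chromosome 4, 48382105 to 48385272) at least 16.3-fold. Pms1 (chromosome 1, 53207576 to 53282092) had 489 reads in wild type P13 and was unlisted in the other 3 libraries, at least 73.1-fold lower in deletion P13. Rbbp4 (chromosome 4, 129317648 to 129322869) had 267 reads in wild type P13, none listed in deletion P13 and 187 and 66 in the P12 libraries. For Pms1 and Rbbp4, 1 library thus differed from the other 3 in whether the circRNA was listed. Their calls rest on that library. The ratio of a Bbs9 circRNA (chromosome 9, 22504045 to 22579593) was 0.0418 (0.00853 to 0.124). Of 8014 tested, 827 were called higher and 768 lower, against 76.9 and 81.3 in simulated unchanged libraries. On the SRPBM scale the split was 34 and 5834.

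Nedd4, Bfsp1, Slc12a5, Ube2cbp and Srsf1 hosted the circRNAs called higher at both days with the largest smaller bound. Those called lower were an intergenic one on chromosome 15 and those of Wdr78, Prkd3, Slc17a5 and Txndc11. Slc12a5 was 19.1-fold higher at P12 (95% counting interval 9.16 to 45.9) and 83.6-fold at P13, and Srsf1 16.4-fold (8.41 to 35.5) and 9.96-fold (5.83 to 18.0). Ube2cbp (chromosome 9, 86422841 to 86427437) was 12.5-fold (6.50 to 26.2) and 10.3-fold (5.95 to 19.0) higher. Prkd3 (chromosome 17, 79012624 to 79013541) had 63 and 49 reads in wild type and none listed in the deletion, at least 9.50-fold and 7.33-fold lower. In all, 311 circRNAs were called higher at both days (72.9 for independent calls), 249 lower (62.7) and 16 in opposite directions (135). Across 6470 circRNAs, which are not independent replicates, the genotype ratios at P12 and P13 had a Pearson r of 0.470 and a Spearman rho of 0.487, and 67.1% lay on the same side of the median.

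**Figure D2:**
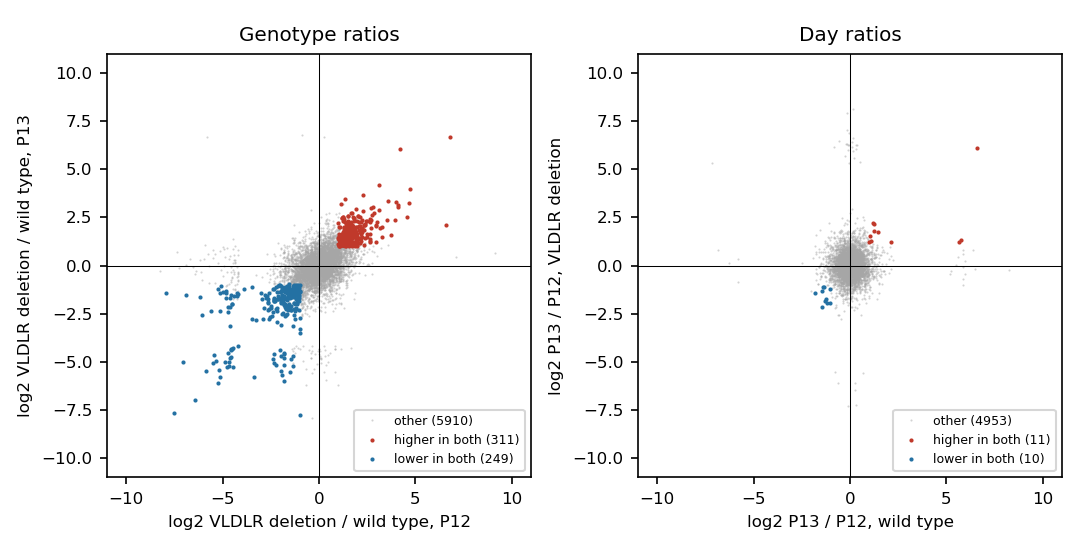
Log2 ratios of TMM-scaled junction reads with 0.5 added, 1 point per circRNA tested in both comparisons: left, VLDLR deletion over wild type at P12 (horizontal) and P13 (vertical); right, P13 over P12 in wild type (horizontal) and in the deletion (vertical). Genotype ratios run along the diagonal (r 0.470; 311 called higher and 249 lower at both days), and day ratios do not (r 0.0289; 11 and 10).

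In wild type, circRNAs of Pms1, Fbxw4, Eed, Cpeb3, Ambra1 and Pcdh15 were called higher at P13 than at P12. CircRNAs of Spopl, Ncoa2, Zfand6, Rock1, Setbp1 and Kcnma1 were called lower. Eed (chromosome 7, 89955531 to 89964862) went from unlisted to 65 reads, at least 19.1-fold higher, and Pcdh15, a photoreceptor and hair-cell cadherin gene (chromosome 10, 74379333 to 74454101), to 43 reads, at least 12.6-fold. Pms1 was at least 144-fold higher, and Spopl, Ncoa2 and Zfand6 were at least 209-fold, 187-fold and 108-fold lower. Pms1 was listed in wild type P13 alone, and Spopl and Ncoa2 in wild type P12 alone. Their calls for the day and for the genotype therefore rest on the same single library. Rock1 (chromosome 18, 10119885 to 10132272) went from 73 reads to unlisted, at least 27.6-fold lower. Of 9794 tested, 439 were called higher and 452 lower, against 91.4 and 89.2 in simulated unchanged libraries, which leave out the spread between libraries. On the SRPBM scale the split was 730 and 269. Between the 2 lanes of wild type P12, 2.82% of circRNAs were called, and between those of wild type P13, 2.86%.

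In the deletion, circRNAs of Emc2, Sltm, Pak3, Sgce and Ube2cbp were called higher at P13 than at P12. CircRNAs of Tle4, Rbbp4, Phkb, Setbp1, Rims2, Rere, Pcsk6 and Prkca were called lower. Emc2 was at least 46.5-fold and Sltm at least 40.0-fold higher. The Emc2 circRNA was unlisted in deletion P12 alone, so that its calls for the day and for the genotype rest on that library. Tle4 (chromosome 19, 14516359 to 14544862) went from 69 reads to unlisted, at least 25.9-fold lower, and the ratio of Pcsk6 was 0.0410 (95% counting interval 0.00825 to 0.125). Of 5206 tested, 208 were called higher and 218 lower, against 50.7 and 51.0 in simulated unchanged libraries.

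From P12 to P13 over both genotypes, Cpeb3 was called higher and Nfic lower, and no other circRNA passed. The Cpeb3 circRNA, from a cytoplasmic polyadenylation regulator gene (chromosome 19, 37087538 to 37126388), was unlisted in both P12 libraries and held 55 and 38 reads at P13 in wild type and the deletion, at least 16.2-fold and 11.3-fold higher. Nfic, a nuclear factor I gene (chromosome 10, 81420267 to 81420798), went from 363 to 129 reads in wild type and from 26 to 15 in the deletion, a log2 fold change of -1.48. Adjusted p were 0.00139 for Cpeb3 and 0.0466 for Nfic (edgeR's quasi-likelihood test, Benjamini-Hochberg), with 158 circRNAs up and 156 down at an unadjusted p under 0.05, and DESeq2 called 0. Fits of 3 libraries had no genotype term, so that genotype differences enter them. Each again took circRNAs with at least 10 reads in at least 2 of its libraries. Cpeb3, unlisted at P12, was therefore not tested in the fits without a P13 library and could not rise there. Without wild type P12, 37 rose and 2 fell, and without deletion P12 15 rose and 0 fell. Without wild type P13 0 rose, and without deletion P13 0 rose and 0 fell. Nfic passed in none of these fits of 3 libraries and had the opposite sign without wild type P12 (log2 0.45, adjusted p 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With near neighbours on the flow cell counted once, Cpeb3 and Nfic did not pass (adjusted p 0.203 and 0.685 by the same test), nor did they without the genotype term or on the SRPBM scale. In each of the 20 lists 0 circRNAs passed by edgeR's test, over all tested and adjusted over the list alone, and DESeq2 called 0. Photoreceptor hosts had 10 up and 2 down and synapse hosts 3 up and 8 down at an unadjusted p under 0.05.

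Cpeb3, the tubulin deglutamylase gene Agtpbp1, Kdm4c and Fstl5 were among the hosts of the circRNAs called higher at P13 in both genotypes with the largest smaller bound. Magi2, Zfp516, Ralgps1, Syt9 and Dhx9 hosted those called lower. Agtpbp1 (chromosome 13, 59460469 to 59462173) was 2.75-fold higher in wild type (95% counting interval 1.57 to 5.07) and 3.56-fold in the deletion (1.42 to 10.6). The ratio of Magi2 (chromosome 5, 19678653 to 19719879, intron class) was 0.357 (0.191 to 0.641) in wild type and 0.209 (0.0512 to 0.642) in the deletion. In all, 11 were called higher in both genotypes (5.39 for independent calls), 10 lower (5.11) and 9 in opposite directions (10.5). Across 4974 circRNAs the day ratios of the genotypes had a Pearson r of 0.0289 and a Spearman rho of 0.0361, and 51.8% lay on the same side of the median.

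Photoreceptor hosts were shifted up from P12 to P13 in both genotypes, with a median log2 ratio of 0.178 over 27 hosts in wild type (98.7 percentile of matched random lists) and 0.186 over 22 in the deletion (98.0). With at least 50 reads, or with circRNAs listed in both libraries, the list was inside the middle 95% in both genotypes. Rdh12, a retinol dehydrogenase gene, was 5.73-fold higher in wild type (95% counting interval 1.99 to 22.6) and Pde6b 2.39-fold (1.34 to 4.44). In the deletion, synapse hosts were shifted down (-0.169, percentile 0.475), with Cacna1c at a ratio of 0.467 (0.313 to 0.687). So were endothelial hosts (-0.316, percentile 2.05), with Fgfr1 at 0.314 (0.101 to 0.834). With single circRNAs in place of host sums neither list was outside the middle 95%, nor were endothelial hosts with at least 50 reads. For the genotype at P12, retinal pigment epithelium and melanocyte hosts were shifted up (0.803, percentile 99.3), although Rgr was called higher (2.95, 1.14 to 7.92) and Oca2 lower (0.312, 0.150 to 0.589). Endothelial hosts were shifted up too (0.448, percentile 98.1), with Plxnd1 at 6.63 (lower bound 3.03) and Sema3a at 2.95 (1.31 to 6.83). At P13 these lists stood at percentiles 46.2 and 78.7. With at least 50 reads, or with circRNAs listed in both libraries, neither list was outside the middle 95% at P12, nor was the pigment epithelium list with single circRNAs. At P13 microglia and leukocyte hosts were shifted up (0.581, percentile 98.0), a shift not outside the middle 95% on the SRPBM scale, with at least 50 reads, with single circRNAs or with circRNAs listed in both libraries. Sag was 3.65-fold higher at P12 (3.14 to 4.24) and 2.98-fold at P13 (2.60 to 3.42). Foxo3 stood at 0.156 (0.0613 to 0.334) and 0.221 (0.103 to 0.423), and Cryga at 0.197 (0.0513 to 0.539) and 0.113 (0.0479 to 0.228). For the genotype, the SRPBM scale lowers each list median by the shift of the scale, which puts all of them below wild type. The photoreceptor shifts between the days stay positive there. Of 16 or 17 lists with at least 3 hosts, 2 lay outside the middle 95% of random lists for the genotype at P12, 1 at P13, 1 for the day in wild type and 3 for the day in the deletion, where 0.80 or 0.85 would by chance.

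**Figure D3:**
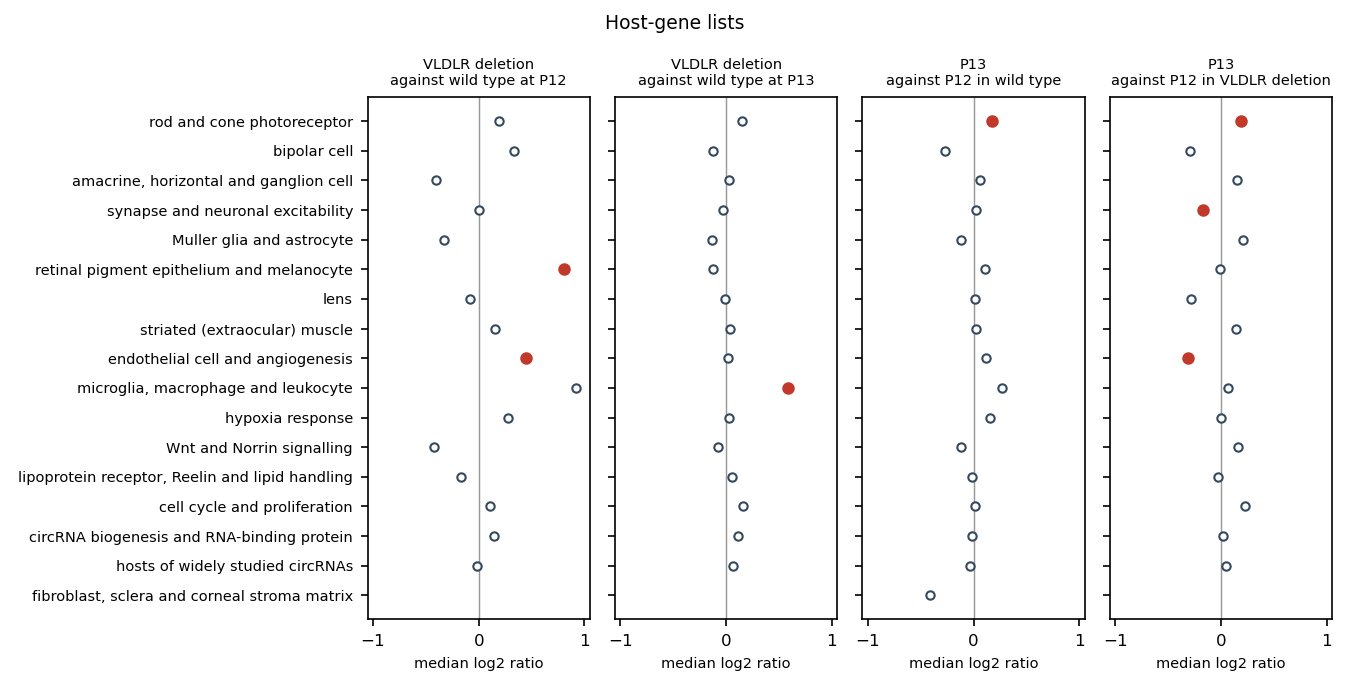
Median log2 ratio of TMM-scaled junction reads per list of host genes (horizontal axis) in the 4 pairs of libraries, for lists with at least 3 hosts. Filled points lie outside the middle 95% of 10000 matched random lists, and photoreceptor hosts are filled in both comparisons of P13 with P12 (0.178 and 0.186); on the SRPBM scale genotype points move by -1.36 at P12 and -1.56 at P13.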

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

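Of the tests in this part, those on the sequencing run, on depth, on linear RNA and on sex were chosen after the results were seen, and those on strain segments and on dropped circRNAs were set before.

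Between the days, 16 circRNAs were called for the genotype in opposite directions, against 135 for independent calls. They included those of Ptpn21 (chromosome 12, 98682519 to 98683615; 35, 18, 6 and 20 reads in wild type P12, wild type P13, deletion P12 and deletion P13) and Mettl15 (66, 42, 0 and 40). Between the genotypes, 9 were called for the day in opposite directions, among them Map4 (44, 20, 13 and 34 reads) and Crim1 (21, 48, 15 and 5). The difference between the contrasts was not tested, since each group held 1 library. Outside the junction reads, Rpph1, the gene of the RNA component of RNase P, held 9030278 non-junction reads in wild type P13 (53.6% of all there) and 10266578 in deletion P13 (82.0%), beside 32 and 17 junction reads. No Rpph1 circRNA was listed at P12, so the tables hold no P12 value to compare.

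The genotype calls of Bfsp1, Sag, Kif1b and Ip6k2 were among those shared by both days. Counting error from the lower depth of the deletion libraries is argued against. With both libraries thinned to the same total, 985 circRNAs were called at P12. Simulated unchanged libraries of the thinned size, which hold counting error only, gave 47.9 higher and 54.0 lower. Thinning used listed counts and cannot reproduce circRNAs that the caller missed at lower depth, so depth stays open for these. Of 769 called lower at P12, 174 were unlisted in the deletion, and of 795 called higher 9 were unlisted in wild type. Genome segments of another strain would place called hosts side by side. The middle 95% of 10000 permutations ran from 80 to 111 adjacent pairs of called hosts, and 110 were found among 3253 hosts. That value lies inside the range set beforehand to argue against such segments, but only just, at percentile 96.4, and was read as undecided after it was seen, so strain segments remain open. The sequencing run, with 0 runs shared between the genotypes, cannot be told apart from the deletion itself, and both remain open.

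Summed SRPBM was 2.57-fold lower in the deletion at P12 and 2.94-fold lower at P13. Linear RNA left over from the same host genes is argued against, since it would bring the median junction ratio to 0.393 at P12 and 0.370 at P13. The ratio was 0.629 and 0.627 in the deletion and 0.624 and 0.634 in wild type. A difference between the runs (0 shared) and the deletion of VLDLR cannot be told apart. Linear RNA from other genes stays open too, because what the SRPBM constant counts is not given in the sources used here.

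Uty and Kdm5d held 219 and 18 junction reads in wild type P12, 300 and 27 in wild type P13, 71 and 6 in deletion P12, and no listed circRNA in deletion P13. All chromosome Y circRNAs together numbered 28, 31, 15 and 0. Dropout of single circRNAs by the caller is argued against, since the chance that all 15 went unlisted, taken from other circRNAs with as many reads, was 3.7e-09. That value takes the 15 as independent, although 12 of them came from Uty and 2 from Kdm5d. It does not cover a loss shared by the circRNAs of a host. A library made from female animals only may be the source. Xist, listed with 5, 6 and 3 reads in the other libraries, was unlisted there too, which has a chance of 0.144 at the level of deletion P12 and of 0.00836 at 2 times that level. Since that level rests on 3 reads, the latter becomes 0.0873 with its counting error included. The sex of the animals, which the labels do not give, stays open. A difference in sex would enter the genotype comparison at P13, the day comparison in the deletion and the fits of all 4 libraries.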

How the results depend on the processing

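The alternatives with circRNAs listed in both or all 4 libraries, and with near neighbours counted once, were chosen after seeing the data. No paired analysis was possible because the groups share 1 replicate number only; the genotype test compared within days through its day term. On simulated data of this spread, 9% of 2-fold changes were recovered by the genotype test. For moved counts the cause was not tested. Other read minimums, sums per host and leaving out a library also change which circRNAs or hosts are tested.

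For the genotype at P12 (795 higher, 769 lower), SRPBM scaling gave 63 and 4660, at least 50 reads 293 and 360, at least 10 reads 1262 and 1904, sums per host 237 and 406, and thinning 447 lower. For the genotype at P13 (827, 768), SRPBM gave 34 and 5834, at least 50 reads 318 and 335, at least 10 reads 1318 and 1801, sums per host 213 and 374, and thinning 451 lower. For the day in wild type (439, 452), SRPBM gave 730 and 269, at least 50 reads 77 and 100, at least 10 reads 900 and 886, and sums per host 158 and 151. For the day in the deletion (208, 218), at least 50 reads gave 39 and 39, at least 10 reads 411 and 427, and sums per host 120 and 109.

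In the genotype test (442 rose, 315 fell), DESeq2 gave 187 and 102, SRPBM 25 and 4773, no filter 260 rose, sums per host 291 rose, and near neighbours counted once (added) 200 fell. Leaving out 1 library at a time gave from 256 to 517 that rose and from 200 to 881 that fell, with no additive term, so that the other factor enters these fits, and with the lone library of a genotype taken to vary like the other pair. In the day test (1 rose, 1 fell), DESeq2, SRPBM and no additive term gave 0 and 0, no filter 7 and 10, a mean of at least 20 reads 2 and 5, sums per host 3 fell, circRNAs listed in all 4 libraries (added) 0 and 4, and near neighbours counted once (added) 0 and 0. At an unadjusted p under 0.05 edgeR had 188 and 51 on the SRPBM scale. Leaving out 1 library gave from 0 to 37 that rose and from 0 to 2 that fell.

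Of the lists outside the middle 95% of random lists, at P12 (2, pigment epithelium and endothelial) there was 1 at 50 reads, microglia, and 1 with circRNAs listed in both (added), Wnt, which was lower. Single circRNAs kept endothelial and gave cell cycle. SRPBM added microglia. At P13 (1, microglia) there were 0 on the SRPBM scale and 2 with circRNAs listed in both, cell cycle and RNA-binding protein; 50 reads and single circRNAs gave cell cycle alone. For the day in wild type (1, photoreceptor) there were 0 at 50 reads, 2 with single circRNAs (RNA-binding protein was lower) and 0 with circRNAs listed in both. For the day in the deletion (3) there was 1 with single circRNAs, photoreceptor. At 50 reads the 3 were bipolar, synapse and lens, all lower, and circRNAs listed in both kept synapse and endothelial. With at least 5 reads the exonic share was 89.7%, 89.6%, 90.4% and 90.4% and the detected number 17572, 19092, 10032 and 10930 (wild type P12, wild type P13, deletion P12, deletion P13). With at least 10 reads the median junction ratios were 0.509, 0.524, 0.520 and 0.528. The r of the genotype ratios was 0.567 at 50 reads, 0.445 per host and 0.532 over circRNAs listed in all 4 libraries (added).

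For Nfic, which fell with day, the fit without wild type P12 gave the opposite sign (log2 0.45, adjusted p 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 19 circRNAs named for the genotype by smallest p, Bbs9, Eri3 and the intergenic one on chromosome 6 no longer passed on the SRPBM scale (adjusted p 0.679, 0.973 and 0.695 by the same test), and none changed direction. Of 43 others named from lists or hosts, 18 that rose had the opposite sign on that scale, 11 no longer passed and 14 passed in the same direction. Of the 18, 5 were called lower there: Zfp292 (adjusted p 0.00556), Kdm4c (0.00620), Ldha (0.0148), Phkb (0.0163) and Cacna2d4 (0.0404), by the same test. The other 13 did not pass there: Tmeff1 (0.131), Rims2 (0.150), Xrcc4 (0.223), Wdr78 (0.234, 0.417 and 0.716), Sorcs1 (0.358), Cngb3 (0.665), Pola1 (0.712), Tfrc (0.816), Bfsp1 (0.856, its weaker circRNA), Dmd (0.886) and Prom1 (0.964). Of the 43, 18 did not pass by DESeq2, 11 without the filter, 6 with no additive term, 8 with near neighbours counted once (added) and between 4 and 13 in fits without 1 library. Among all 442 that rose, 68 were called lower on the SRPBM scale, where every genotype list median lay below wild type. Of the values of comparisons, 66 planned and 21 added ones stayed within their range and 80 and 9 moved. Of the values of single circRNAs and lists (the 43 on the SRPBM scale only), 461 planned ones kept their side of the threshold, 8 passed only under the alternative, 35 no longer passed and 19 reversed, and of the added ones 93, 3 and 7 did the first 3.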

Other observations

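The hosts with circRNAs in both directions and the motile-cilium hosts were singled out after their values were seen, and the test of the motile-cilium list was set before its median was computed.

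Kmt2a, Pik3c2a, Tmeff1, Pitpnm3, Xrcc4 and Wdr78 were among 33 hosts with 1 circRNA that rose and another that fell in the deletion. In Pik3c2a a circRNA (chromosome 7, 116358636 to 116360100) rose by 4.02 on the log2 scale, from 10 and 13 reads in wild type P12 and P13 to 122 and 56 in deletion P12 and P13, and another (116359996 to 116368189) fell by 0.92, from 163 and 245 reads to 42 and 54. In Tmeff1 one (chromosome 4, 48604581 to 48617331) fell by 1.20, from 697 and 736 reads to 125 and 158, and one (48636840 to 48650418) rose by 1.07. In Xrcc4, a DNA repair gene, both shared the start at 89991073 on chromosome 13: the one ending at 89992606 rose by 1.15 and the one ending at 90001084 fell by 1.54. Wdr78 had 3 that rose and 1 that fell of 6, and the intergenic circRNA on chromosome 15 (84171082 to 84186081) was unlisted in both deletion libraries. These directions are relative to the median circRNA, and on the SRPBM scale 68 of the 442 that rose were called lower. The rises of Tmeff1 (-0.38 there), Xrcc4 (-0.30) and Wdr78 had the opposite sign on that scale.

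Dnah9, Iqub and Armc2, genes of motile cilia, rose on reads summed per host in the deletion (log2 3.10, 2.78 and 2.41; Dnah9 from 22 and 14 reads to 52 and 85), while Dnaaf4 and Dnaic2 did not pass, so that motile-cilium hosts may have risen as a list. Without these 5 genes the list median was 0.279 over 9 hosts at P12 (percentile 89.6 of matched random lists) and 0.104 over 12 hosts at P13 (percentile 84.4), both inside the middle 95%. Of its circRNAs, relative to the median circRNA, 4 rose and 1 fell of 15 (6 and 1 adjusted over the list alone), and DESeq2 called 2. Wdr78 gave 3 of those that rose and the 1 that fell. On summed reads 2 of 11 hosts rose, Rfx3 and Wdr78, and 0 fell by edgeR (3 and 0 at an unadjusted p under 0.05). On the SRPBM scale both hosts were called lower (-1.13 and -0.53). Of the genes noticed first, Dnah9 passed as higher on that scale (1.59), and Iqub (1.27) and Armc2 (0.89) did not pass. Both percentiles met the bound set beforehand against a shift of the list, but that bound excludes nothing in a list of so few hosts that left out called genes. A shift therefore remains open. Wdr78, in the remaining list, had been seen before.

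Split by genotype without the other term, edgeR called 633 of the 8785 circRNAs, and the highest of the other splits called 0 (1965 against 41 at an unadjusted p under 0.05). In the other splits each side mixed the genotypes, and with them the sequencing runs. That difference then entered the residual spread, which lowers the number of calls there. The other splits are therefore no baseline for the 633, and no conclusion on the genotype was drawn from them. The 4 libraries also allow only 3 splits, too few for a share under 0.05. Of circRNAs with at least 30 reads in wild type P12, 71 of 3620 were unlisted in deletion P12 and 12 in wild type P13, and of those in deletion P12, 4 of 1736 were unlisted in wild type P12 and 7 in deletion P13.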
